A study of Homo sapiens with 2 samples.

How the data were processed

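Total RNA from cultured human mesothelioma cells was measured on 2 arrays of 2 colours each. On the first array, ACC-MESO1 cells depleted of CD26 were compared with control ACC-MESO1 cells. On the second, MSTO-211H cells transfected with CD26 in the vector pLNCX2 were compared with control MSTO-211H cells. ACC-MESO1 and MSTO-211H are established mesothelioma cell lines. The labels call the depleting agent an siRNA in one place and an shRNA in another, and do not say what the control cells received. Per the labels' protocols, RNA was extracted with TRIZOL, amplified with an amino allyl kit, and coupled to dyes. On both arrays Cy5 carried the control cells and Cy3 the manipulated cells. There was no dye swap and no replicate array. A gene-specific dye effect would therefore give a gene the same sign on both arrays.

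The deposited values are normalized log2 ratios of the manipulated cells over the control cells, and this direction is given by the authors in the sample descriptions. Each array had a median log2 ratio of 0 over its probes, so the values had already been centred. The background correction, the normalization method, the scanner and the rule for leaving a probe without a value are not given in the sources used here. Channel intensities were not used here, so a bright probe could not be told from a dim one, and no intensity filter or matching on expression was possible.

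The table held 24267 probes, of which 19622 had a value on the depletion array and 17737 on the transfection array. Both arrays gave a value for 16845 probes, and 3753 had none on either. The probe annotation gave 1 gene symbol for 13395 probes, several for 0 and none for 10872. Symbols were updated through the RefSeq annotation of GRCh38.p14. Of the distinct symbols, 10076 were current, 2281 were updated through a synonym, and 117 with several candidates were kept as listed. Probes of a gene were averaged. This gave 10347 genes on the depletion array and 9359 on the transfection array, with 8956 on both. The names of 57 probes give positions along a transcript with a median length of 70 bases. Probes of that kind can cross-hybridise among close paralogs.

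With 1 array per group, no p-value, standard error or replicate SD can be given, and the number of arrays limits the precision of every value. The only repeat measurement was the agreement of different probes of a gene. Among the 566 genes with several probes on the depletion array, the pooled SD between probes of a gene was 0.42 on the log2 scale. It was 0.45 among 471 such genes on the transfection array. For genes with exactly 2 probes, the correlation between the probes was 0.28 over 495 genes on the depletion array and 0.18 over 411 genes on the transfection array. The SD over all probes was 0.48 and 0.50.

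Genes were called higher or lower at a log2 ratio of at least 1 in size, which is 2-fold. Thresholds of 0.5 and 1.5 were alternatives. For genes past the threshold on both arrays, the observed number is set beside the number that independent lists would share. Apart from genes said to be named after their values were seen, the genes named in the text follow a rule written before the data were examined. It took DPP4, POSTN, TWIST1 and SRC, the 12 highest and 12 lowest genes of each array, the 10 genes of each opposite class with the largest smaller absolute log2 ratio, the extreme members of gene lists that stood apart, and the members past 2-fold of lists discussed. Symbols that are placeholders for uncharacterised genes were left out of the ranked parts.

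Also before the data were examined, 29 gene lists were fixed, 25 of pathways and 4 of markers of other cell types. They held 736 distinct genes, of which 622 were named on the array, and 46 genes were in more than 1 list. For each list and array, the median log2 ratio of the measured members was set against 10000 random lists of the same size from the genes of that array. A list was said to stand apart when its median was at or outside the 2.5th or 97.5th percentile. By chance 2.9 of the 58 evaluations would do so if list members were independent, and genes of a list are not independent, so the percentile describes these arrays and is no test of the conditions. The interval given with a list median is the 95% order-statistic interval over its members, and it covers the spread between genes only. In simulated lists of 20 genes drawn from the depletion array, a shift of 0.4 was recovered in 97.0% of 200 lists and a shift of 0.2 in 50.5%. On the transfection array the same shifts were recovered in 98.0% and 50.0%. In lists of 10 genes, a shift of 0.4 was recovered in 80.5% on the depletion array and 69% on the transfection array, and a shift of 0.2 in 30% and 19%. Smaller lists were not simulated.

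Alternatives were another centring, a common spread for both arrays, other rules for probes of a gene, and restriction to genes measured on both arrays. Added after the data were seen were a centring by chromosome, lists without members past 2-fold, the omission of tissue-restricted families and the correlation over all probes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.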

Results

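The data were log2 ratios from 2 arrays that asked how gene expression in mesothelioma cells differs when CD26 is lowered or raised. CD26, encoded by DPP4, is a cell surface dipeptidyl peptidase. The first array set CD26-depleted ACC-MESO1 cells against their control (n = 1 array), and the second set CD26-transfected MSTO-211H cells against theirs (n = 1 array). A gene had a measured value on the depletion array in 10347 cases and on the transfection array in 9359 cases. No comparison below has a replicate, so each value is that of a single pair of RNA samples. All values are log2 ratios of manipulated over control cells, relative to an array median of 0.

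DPP4 itself was 15.1-fold lower in the depleted ACC-MESO1 cells (log2 ratio -3.92) and 45.7-fold higher in the transfected MSTO-211H cells (log2 ratio 5.51). It was the lowest of all named genes on the depletion array and the highest on the transfection array. Both values came from the same single probe and went in the direction of the labels; whether that probe lies in the transfected sequence is not given in the sources used here. No other measured member of the DPP family was past 2-fold in the direction of DPP4. FAP, fibroblast activation protein, had a log2 ratio of 0.71 in depleted cells and -1.76 in transfected cells, opposite to DPP4 on both arrays. As a list, the DPP family had a median of 0.09 after depletion and 0.06 after transfection, at the 70.3rd and 61.3rd percentile of random lists. With the probe of largest absolute ratio per gene, the depletion median was 0.48, at the 99.5th percentile, and the list stood apart as higher.

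Periostin, the matrix protein encoded by POSTN, was 11.8-fold higher in the CD26-transfected MSTO-211H cells (log2 ratio 3.57) and second only to DPP4 among named genes there. In CD26-depleted ACC-MESO1 cells its log2 ratio was -0.23, within the pooled SD of 0.42 between probes of a gene. TWIST1, a transcription factor of mesenchymal cells, had a log2 ratio of -0.76 after depletion and no value on the transfection array. The kinase gene SRC had -0.07 and 0.27. The list of periostin, Twist and Src related genes did not stand apart on either array, with medians of -0.02 and 0.10. LOX, a collagen cross-linking enzyme, was the member past 2-fold after depletion (1.82). After transfection, POSTN was joined past 2-fold by the secreted matrix protein gene TGFBI, which was lower (-1.05).

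After CD26 depletion, 342 of the 10347 genes were at least 2-fold higher and 161 at least 2-fold lower in ACC-MESO1 cells. The numbers were 853 and 42 when the array was centred on ribosomal protein genes, which moved all genes and list medians of this array up by 0.35. Among genes measured on both arrays, 203 were at least 2-fold higher. The highest included the matrix metalloproteinase MMP3 (log2 ratio 3.75, 13.5-fold), the chemokine CCL5 (3.27, 9.67-fold), GLIPR1 (3.11), TMEM40 (2.93), the matricellular protein gene CCN2 (2.83), the growth factor FGF1 (2.81), BEST4 (2.78), the apoptosis inhibitor BIRC3 (2.77), the transglutaminase TGM2 (2.63), BTG4 (2.56) and the TNF receptor adaptor TRAF1 (2.52). The olfactory receptor gene OR1E2 (3.24) was also among these 12, and belongs to a family of close paralogs. Of the 12, 7 had no value on the transfection array. Genes with a value on the depletion array alone were past 2-fold in 13.2% of 1391 cases, against 3.56% of the 8956 genes measured on both. The lowest after DPP4 were INSIG1, a regulator of sterol synthesis (-2.40, 5.26-fold), the histamine-degrading enzyme HNMT (-2.13), the glutaredoxin GLRX (-2.11), the transcription factor GATA4 (-2.10), EXOC4 (-1.98), ASB9 (-1.97), DOCK11 (-1.93), the phosphatidate phosphatase LPIN1 (-1.92), the histone gene H2AC6 (-1.91), LETM1 (-1.88) and CIB2 (-1.82). All 24 rested on a single probe. Among the genes with several probes whose mean was past 2-fold on this array, 5 of 11 had every probe past it.

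Of the 29 fixed gene lists, 6 stood apart as higher and 4 as lower in the depleted cells. Targets of the transcriptional regulators YAP and TEAD had a median log2 ratio of 0.70 (interval over members 0.12 to 1.15), and 14 of 15 measured members were above 0. CCN2 (2.83), the coagulation initiator F3 (1.51, with probes at 1.35 and 1.66), GADD45A (1.35) and the ectonucleotidase NT5E (1.15) were past 2-fold, and the lowest were LATS2 (0.02) and PTPN14 (-0.05). Cytokines and NF-kB targets had a median of 0.48 (0.25 to 1.22), with 20 of 23 above 0 and 7 past 2-fold. These were CCL5 (3.27), BIRC3 (2.77), the neutrophil chemokines CXCL1 (2.46), CXCL8 (1.60) and CXCL2 (1.33), the NF-kB subunit gene RELB (1.25) and its feedback inhibitor TNFAIP3 (1.22). The 2 probes of CXCL8 differed, at 0.09 and 3.11. SOD2 (-0.18) and CSF3 (-0.61) were the lowest members. TGF-beta targets had a median of 0.30 (-0.13 to 0.85), with CCN2 (2.83), the actin-binding protein gene TAGLN (1.89), THBS1 (1.40) and LTBP2 (1.17) at least 2-fold higher, and ID3 (-1.01) and SMAD6 (-1.24) at least 2-fold lower. Among genes measured on both arrays, that list's median was 0.22, at the 97.1st percentile, and it no longer stood apart.

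Interferon-stimulated genes had a median of 0.56 (0.35 to 0.72) in depleted cells, with 26 of 31 above 0. Those past 2-fold were IFI27 (2.04), ISG15 (1.48), the immunoproteasome subunits PSMB8 (1.25) and PSMB9 (1.17), IFI6 (1.16), the RNA sensor RIGI (1.13), IFIT3 (1.07) and the peptide transporter TAP1 (1.05). IFIT1 (-0.55) and MX1 (-0.67) were the lowest. Cell cycle inhibitors and p53 targets had a median of 0.23 (-0.23 to 0.48), led by GADD45A (1.35), the CDK inhibitor CDKN1A (1.28) and SESN2 (1.02), while CCNG1 (-0.84) and CDKN2C (-0.95) were the lowest. Matrix genes had a median of 0.22 (-0.15 to 0.60), with THBS1 (1.40), the fibrillin FBN2 (1.36) and the collagen COL7A1 (1.14) past 2-fold and NID1 (-0.86) and LUM (-0.89) the lowest. Matrix proteases and their inhibitors did not stand apart as a list (median 0.19, at the 95.8th percentile), but 6 of 21 were past 2-fold, namely MMP3 (3.75), MMP10 (2.23), the urokinase receptor PLAUR (1.69), urokinase PLAU (1.41), TIMP1 (1.30) and MMP1 (1.25).

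Genes of sterol synthesis and uptake were the list farthest below 0 after CD26 depletion, with a median of -0.55 (-1.02 to -0.15), or -0.19 when the array was centred on ribosomal protein genes, and as deposited only TM7SF2 (0.25) of 19 was above 0. INSIG1 (-2.40), the cholesterol synthesis enzymes HMGCS1 (-1.21), MSMO1 (-1.08), IDI1 (-1.06) and LSS (-1.02) were at least 2-fold lower. Ribosomal protein genes had a median of -0.35 (-0.57 to -0.24), with RPLP0 (-1.36) and RPS2 (-1.05) past 2-fold and RPS19 (0.33) and RPL34 (0.32) the highest. These genes have many pseudogenes, and their probes are open to cross-hybridisation. Oxidative phosphorylation genes had a median of -0.19 (-0.25 to -0.07), or 0.16 when the array was centred on ribosomal protein genes, from NDUFS8 (0.39) and COX5A (0.25) to UQCRFS1 (-0.53) and COX8A (-0.62). Mitotic genes had a median of -0.19 (-0.44 to -0.04), or 0.16 with that centring, and none past 2-fold, from UBE2C (0.68) and AURKB (0.43) to DLGAP5 (-0.74) and the survivin gene BIRC5 (-0.82). Replication genes lay on the other side of 0 (median 0.15, at the 95.6th percentile), without standing apart.

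Lists that did not stand apart after depletion included mesothelial markers (median 0.06), although the intelectin ITLN1 (1.38) and the cadherin CDH3 (1.35) were past 2-fold. Mesenchymal genes were at the 97.2nd percentile (median 0.22), but stood apart as higher among genes measured on both arrays (0.42, at the 99.96th percentile), with TAGLN (1.89), LOX (1.82), the integrin ITGA5 (1.29) and S100A4 (1.15) past 2-fold. Epithelial junction genes had a median of -0.06, with CLDN1 (2.32) and CDH3 (1.35) past 2-fold. Markers of fibroblasts (-0.08), lymphocytes (-0.01), myeloid cells (0.13) and endothelial cells (-0.07) did not stand apart either. MFAP5 (1.96), a fibroblast marker, was the member of these 4 lists past 2-fold.

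After CD26 transfection, 383 of the 9359 genes were at least 2-fold higher and 128 at least 2-fold lower in MSTO-211H cells. The numbers were 685 and 53 when the array was centred on ribosomal protein genes, which moved all genes and list medians of this array up by 0.25. After DPP4 and POSTN, the highest were the chloride channel gene ANO2 (log2 ratio 3.56, 11.8-fold), ATP6V1G3 (2.72), the imprinted gene NDN (2.68), the endothelin-converting enzyme ECE1 (2.56), the glycogen synthase GYS2 (2.53), the matrix protein EFEMP1 (2.45), TMEM63C (2.36), MMRN1 (2.35), PWWP2B (2.35) and SALL2 (2.30). Leaving out C19orf33 (-2.50), a placeholder symbol named after its value was seen, the lowest were the prostaglandin E synthase PTGES (-2.63, 6.18-fold), the aldo-keto reductase AKR1B10 (-2.44), the retinal reductase DHRS3 (-2.42), the homeobox gene HOXA7 (-2.34), the chromatin remodeller SMARCA1 (-2.05), the basement membrane protein NID2 (-2.02), the lipid droplet protein PLIN2 (-1.98), NMB (-1.85), GALC (-1.77), FAP (-1.76), UNC93B1 (-1.70) and GYPC (-1.70). Each of the 12 highest and 12 lowest genes, DPP4 and POSTN included, rested on a single probe on this array. Among genes with several probes whose mean was past 2-fold on this array, 1 of 8 had every probe past it. Genes with a value on this array alone were past 2-fold in 31.8% of 403 cases, against 4.28% of the 8956 genes measured on both.

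Of the 29 lists, 3 stood apart as higher and 6 as lower in the transfected cells. Matrix proteases and inhibitors had a median of 0.40 (-0.34 to 0.69), with the gelatinase MMP2 (1.77), ADAM19 (1.57) and PLAU (1.21) at least 2-fold higher and TIMP3 (-1.21) and MMP24 (-1.56) at least 2-fold lower. Mesenchymal genes had a median of 0.30 (-0.23 to 0.75), with POSTN (3.57), the collagen COL3A1 (1.78) and MMP2 (1.77) at least 2-fold higher and the transcription factor ZEB2 (-1.16) at least 2-fold lower. This list did not stand apart with each autosome centred on its own median (97.2nd percentile). Interferon-stimulated genes had a median of 0.37 (0.13 to 0.63), with 25 of 30 above 0. ISG15 (1.64), IFIT1 (1.60), IFIT3 (1.46) and IFI27 (1.22) were past 2-fold, and RSAD2 (-0.28) and IRF1 (-0.58) were the lowest.

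Fibroblast markers had a median of -0.53 (-0.77 to 0.75) over 8 genes, with COL14A1 (-0.77) and FBLN1 (-0.71) the lowest and THY1 (0.75) and PI16 (0.42) the highest. Endothelial markers had a median of -0.40 (-0.51 to 0.57) over 6 genes, from CLDN5 (0.57) and ENG (-0.13) to KDR (-0.42) and ERG (-0.51). None of the members of these marker lists were past 2-fold. Cell cycle inhibitors and p53 targets had a median of -0.27 (-0.42 to -0.07), or -0.017 when the array was centred on ribosomal protein genes, and as deposited 5 of 21 were above 0. TP53I3 (1.26) was the member past 2-fold, CCNG1 was at 0.37, and BBC3 (-0.46) and RRM2B (-0.56) were the lowest. Ribosomal protein genes had a median of -0.25 (-0.44 to -0.11), with RPLP1 (-1.03) and RPLP0 (-1.46) past 2-fold and RPL34 (0.26) and RPL22 (0.16) the highest. Sterol genes had a median of -0.22 (-0.43 to -0.09), or 0.028 when the array was centred on ribosomal protein genes, with INSIG1 (-1.33) past 2-fold, IDI1 at -0.51, and STARD4 (0.25) and EBP (0.17) above 0. Replication genes had a median of -0.17 (-0.26 to 0.07), or 0.077 with that centring, from MCM10 (0.70) and POLA2 (0.28) to CDC45 (-0.56) and CCNE1 (-0.71). With each autosome centred on its own median, neither of these 2 lists stood apart.

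Mesothelial markers did not stand apart after transfection (median 0.10), but mesothelin, MSLN (-1.31), and the keratin KRT18 (-1.16) were at least 2-fold lower. Matrix genes had a median of -0.17, at the 3.4th percentile, but stood apart as lower among genes measured on both arrays (-0.23, at the 1.005th percentile) and with each autosome centred on its own median (-0.27, at the 0.3rd percentile), with the proteoglycan BGN (2.20) and COL3A1 (1.78) at least 2-fold higher and LAMA5 (-1.21) and NID2 (-2.02) at least 2-fold lower. Epithelial junction genes had a median of 0.21, with cingulin, CGN (2.10), and PKP2 (1.10) past 2-fold. YAP and TEAD targets (-0.07), TGF-beta targets (-0.14), cytokines and NF-kB targets (-0.14), mitotic genes (0.03) and oxidative phosphorylation genes (0.04) did not stand apart. Among YAP and TEAD targets AMOTL2 (1.02) was at least 2-fold higher and FOXF2 (-1.05) at least 2-fold lower, and among TGF-beta targets TGFBI (-1.05) was at least 2-fold lower. Within the cytokine list, CCL5 (1.85) and CXCL1 (1.54) were at least 2-fold higher and IL1B (-1.68) at least 2-fold lower. Lymphocyte markers (0.07) and myeloid markers (-0.17) did not stand apart, and CD3E (1.88) was the lymphocyte marker past 2-fold.

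**Figure D1:**
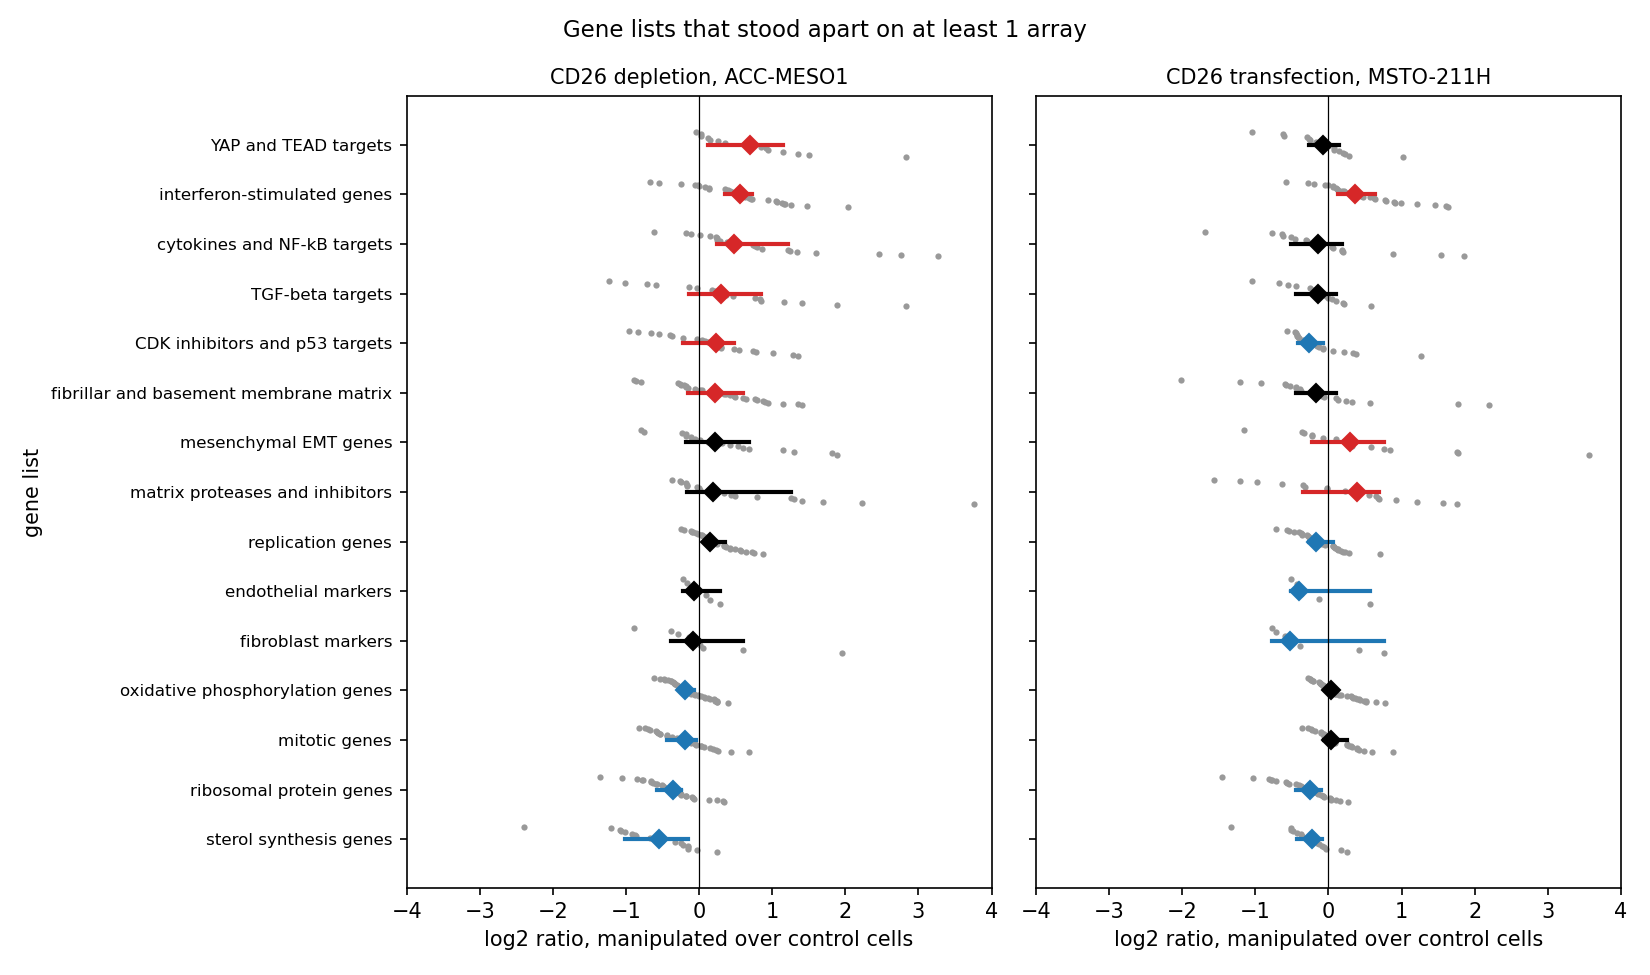
Log2 ratio of manipulated over control cells (x axes) for the measured members of each gene list (y axis) that stood apart on at least 1 array, in CD26-depleted ACC-MESO1 cells on the left and CD26-transfected MSTO-211H cells on the right, where grey points are single genes, spread vertically for legibility, diamonds are list medians and thick lines their 95% order-statistic intervals; red and blue mark lists that stood apart as higher and lower on that array, and black those that did not. Interferon-stimulated genes lie above 0 on both arrays (medians 0.56 and 0.37) and sterol synthesis genes below 0 on both (-0.55 and -0.22, the latter 0.028 when centred on ribosomal protein genes), whereas YAP and TEAD targets are above 0 on the left (0.70) and near 0 on the right (-0.07).

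The design lowered CD26 in a first cell line and raised it in a second, so a gene that followed CD26 would have opposite signs on the 2 arrays. Among the 8956 genes measured on both, 12 were at least 2-fold lower after depletion and at least 2-fold higher after transfection, against 3.47 if the lists were independent. After DPP4, these were led by the Cdk-binding protein gene CABLES1 (log2 ratios -1.57 and 1.46), the RNA-binding protein gene RBM10 (-1.34 and 1.43), the mitochondrial threonyl-tRNA synthetase gene TARS2 (-1.24 and 2.18), NET1 (-1.29 and 1.18), SUCO (-1.18 and 1.22), the Wnt ligand gene WNT7B (-1.71 and 1.14), RAB3D (-1.14 and 1.08), FGFBP3 (-1.05 and 1.31) and SEC24A (-1.04 and 1.57). The 2 probes of CABLES1 on the transfection array were at 0.69 and 2.23. IGFBP7, a secreted IGF-binding protein, was also in this class (-1.01 and 1.99).

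In the other opposite class, 5 genes were at least 2-fold higher after depletion and at least 2-fold lower after transfection, against 2.61 if independent. They were the chondroitin sulfotransferase gene CHST11 (1.19 and -1.23), SUN3 (1.90 and -1.17), the cytidine deaminase gene CDA (1.10 and -1.08), the AXL ligand gene GAS6 (1.07 and -1.37) and C19orf33 (1.09 and -2.50), the last named after its values were seen. Next by the same rule, with 1 of the values short of 2-fold, came TAPBPL (1.27 and -0.94), COL7A1 (1.14 and -0.93), EMP1 (1.94 and -0.88), AADAC (1.23 and -0.86), the stress cytokine GDF15 (1.77 and -0.86) and TGFBI (0.85 and -1.05).

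The classes with the same sign on both arrays also exceeded their expectation. There were 25 genes at least 2-fold higher on both, against 6.07 if independent. They included CCL5 (3.27 and 1.85), CXCL1 (2.46 and 1.54), ISG15 (1.48 and 1.64), IFI27 (2.04 and 1.22), IFIT3 (1.07 and 1.46), PLAU (1.41 and 1.21) and ANO2 (1.61 and 3.56). Others, named after their values were seen, included SLC3A1 (2.03 and 1.46), DSG1 (1.59 and 1.61), SERPINI2 (1.59 and 1.36) and TREML1 (1.13 and 1.74). A gene-specific dye effect, with the same dye orientation on both arrays, would also place genes in the classes with a shared sign. There were 5 genes at least 2-fold lower on both, against 1.49 if independent. These were INSIG1 (-2.40 and -1.33), H2AC6 (-1.91 and -1.37), RPLP0 (-1.36 and -1.46), the matrix Gla protein gene MGP (-1.18 and -1.48) and EYA4 (-1.03 and -1.18). MGP and EYA4 were named after their values were seen. The observed number was 3.46 and 1.92 times the expected number in the opposite classes and 4.12 and 3.36 times in the classes with a shared sign. With both arrays centred on ribosomal protein genes, 84 genes were higher on both and 3 lower on both, and the opposite classes held 7 and 4. That centring also changes the number of genes called on each array. Expected numbers were not computed for it, so these counts do not show a change in excess.

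**Figure D2:**
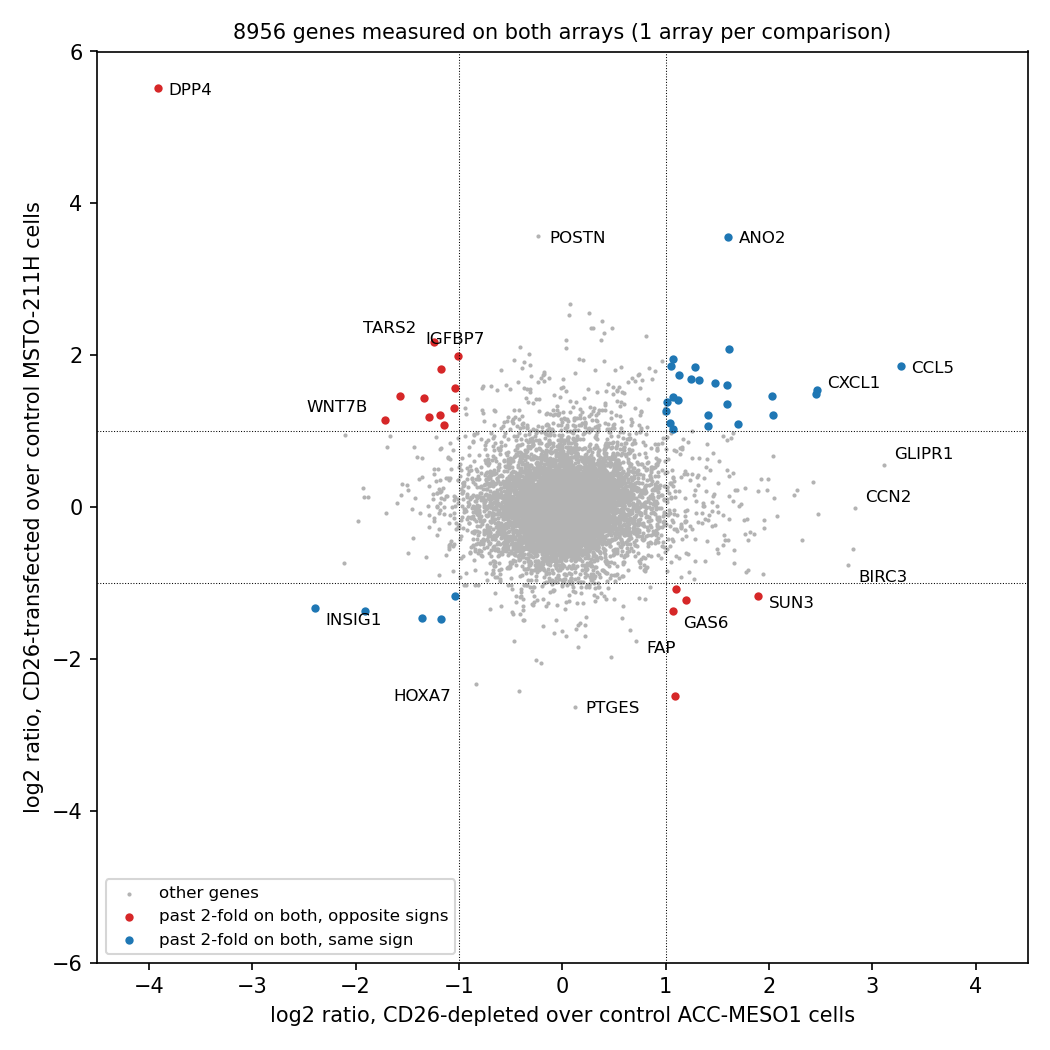
Log2 ratio in CD26-depleted over control ACC-MESO1 cells (x axis) against CD26-transfected over control MSTO-211H cells (y axis) for the 8956 genes measured on both arrays, each point a gene. Red points are genes past 2-fold on both arrays with opposite signs (12 at the upper left, 5 at the lower right), blue points those with the same sign (25 and 5), and dotted lines mark 2-fold; DPP4 lies alone at -3.92 and 5.51.

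Across these genes the log2 ratios of the 2 arrays were nearly unrelated, with a Pearson correlation of 0.06 and a Spearman correlation of 0.08. Over all probes, named or not, the Pearson correlation was 0.11. For genes with 2 probes, the probes correlated at only 0.28 on the depletion array and 0.18 on the transfection array. A low correlation between the arrays therefore does not by itself show that the responses were unrelated. The absolute values correlated at 0.18 (Spearman 0.11), so the sizes of the ratios on the 2 arrays were not independent, which the expected numbers of the 4 classes assume. Genes are not independent replicates, and no p-value is given. The difference between the arrays (depletion minus transfection, for members measured on both) was computed within each of the 29 lists. Named here are the lists whose interval excluded 0, with interferon-stimulated and ribosomal protein genes besides. For the other lists the interval included 0 or could not be given. The median difference was 0.65 (0.28 to 1.40) for YAP and TEAD targets and 0.64 (0.39 to 0.92) for cytokines and NF-kB targets. Both lists stood apart on the depletion array alone, so their difference partly follows from that. As deposited, 8 of 15 members of the YAP and TEAD list were above 0 after depletion and below 0 after transfection, and 0 the other way round. Replication genes differed by 0.43 (0.05 to 0.58), with 17 of 33 above 0 after depletion and below 0 after transfection as deposited. Such counts depend on the zero point. Centred on ribosomal protein genes, the medians after depletion and transfection were 0.50 and 0.077 for replication genes and 1.05 and 0.18 for YAP and TEAD targets. Matrix genes differed by 0.47 (0.02 to 0.88), immediate early genes by 0.46 (0.12 to 0.70) and growth factors and receptors by 0.28 (0.05 to 0.42). Oxidative phosphorylation genes differed by -0.25 (-0.27 to -0.19). Interferon-stimulated genes were above 0 on both arrays for 22 of 29 members, with a difference of 0.24 whose interval included 0 (-0.16 to 0.43). As deposited, sterol genes were below 0 on both arrays for 15 of 18 members, with a difference of -0.29 (-0.60 to -0.06). Ribosomal protein genes were below 0 on both for 24 of 32, with a difference of -0.07 whose interval included 0 (-0.19 to 0.10).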

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

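No paired analysis was possible because each group had 1 array. The restriction by gene family, the centring by chromosome, the omission of members past 2-fold and the use of unnamed probes were chosen after the data were seen, and the other settings before. The DPP4 ratios stayed on their side of 0 in the settings run for them (both centrings and the largest probe). These settings could not have turned them, since DPP4 had a single probe and the centrings moved values by 0.35 at most. Centring on the array median moved nothing because the deposited medians were 0. A threshold of 0.5 gave 1323 genes higher and 1014 lower after depletion, 1224 higher and 880 lower after transfection, 122 and 93 in the opposite classes (lower then higher, higher then lower), and 196 higher and 97 lower on both arrays. At 0.5 the numbers if independent were 88.9 and 92.8 in the opposite classes, and 110.4 higher and 74.7 lower on both arrays. The second opposite class was close to its expectation, and the class higher on both had the largest ratio (1.78). A threshold of 1.5 gave 125 higher and 22 lower after depletion, 141 higher and 22 lower after transfection, 1 (DPP4) and 0 in the opposite classes, and 5 higher and 0 lower on both arrays. Centring on ribosomal protein genes moved all genes up by 0.35 on the depletion array and 0.25 on the transfection array. It gave 853 higher and 42 lower after depletion (95.3% higher, against 68.0% as deposited), 685 higher and 53 lower after transfection (92.8%, against 74.95%), 7 genes lower on depletion and higher on transfection, 84 higher on both and 3 lower on both. It turned the sign of 4 medians that stood apart, to 0.16 for mitotic genes and 0.16 for oxidative phosphorylation genes after depletion, and to 0.0769 for replication genes and 0.0282 for sterol genes after transfection, while percentiles kept their values since every gene moved alike. The ribosomal list itself is 0 there by construction. Restriction to genes measured on both arrays left 203 higher after depletion. The correlation across genes was 0.11 over all probes, named or not. Of the 10 lists that stood apart after depletion, TGF-beta targets did not among genes measured on both arrays, where immediate early and mesenchymal genes did in addition, as did the DPP family with the largest probe per gene. Of the 9 after transfection, mesenchymal, sterol and replication genes did not stand apart with each autosome centred on its own median, and matrix genes did in addition there and among genes measured on both arrays. In the settings other than the omission of members past 2-fold, the number of lists standing apart ranged from 10 to 11 after depletion and from 7 to 10 after transfection. Leaving out members past 2-fold gave 8 lists after depletion, without YAP and TEAD targets and without CDK inhibitors and p53 targets. After transfection it gave 7, without mesenchymal and sterol genes. It takes away the genes that made a list differ, so nothing is drawn from it. Without intensities, the share of calls made by dim probes is open.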

Other observations

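The tests below that were chosen only after the result was seen are the bootstrap of a difference for interferon-stimulated genes, those of a shared dye effect and of growth state for YAP and TEAD targets, and of an effect common to both arrays for chromosomes. Among growth factors and receptors, FGF1 (2.81), the IGF-binding protein gene IGFBP4 (2.03), GAS6 (1.07) and VEGFC (1.05) were at least 2-fold higher after CD26 depletion and IGFBP7 (-1.01) at least 2-fold lower, while the list's median was 0.07. After transfection IGFBP7 was at 1.99 and GAS6 at -1.37, with a list median of -0.08. Immediate early genes had a median of 0.16 after depletion, and stood apart as higher among genes measured on both arrays (0.22, at the 99.0th percentile), with KLF2 (1.78), the phosphatases DUSP4 (1.39) and DUSP1 (1.38), IER3 (1.04) and JUN (1.03) at least 2-fold higher and EGR2 (-1.20) at least 2-fold lower. None were past 2-fold after transfection, where the median was -0.09. Among unfolded protein and amino acid stress genes, the serine synthesis enzyme PHGDH (-1.50), VLDLR (-1.29) and SLC7A11 (2.01-fold) were at least 2-fold lower and SESN2 (1.02) at least 2-fold higher after depletion. The list's medians were -0.12 and 0.03.

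The remaining lists did not stand apart on either array as deposited. Integrins had medians of 0.07 and 0.12, with ITGA5 (1.29) past 2-fold after depletion and ITGA7 (-1.10) after transfection. Proteins that bind CD26 or are cut by it had medians of 0.23 and -0.08, with CCL5 past 2-fold on both arrays (3.27 and 1.85) and CXCL9 (1.61) after depletion. Hypoxia and glycolysis genes had medians of 0.05 and -0.01, with ANGPTL4 (1.63) past 2-fold after depletion and GAPDH (-1.39) after transfection. Tumour initiating cell markers had medians of -0.06 and -0.18, with NT5E (1.15) and CD9 (1.03) past 2-fold after depletion and SOX2 (1.04) after transfection. RNA polymerase II subunits had medians of -0.11 and 0.00.

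On the transfection array, the rank correlation between neighbouring autosomal genes, in the gene order of GRCh38.p14, was 0.08, above the highest of 1000 shuffled gene orders (0.04), and 7 of 22 autosomes had a median outside the range of all shuffles. Chromosomes 14 (0.21), 2 (0.13), 5 (0.12) and 8 (0.10) lay above it, and chromosomes 13 (-0.25), 7 (-0.17) and 22 (-0.13) below. Tandem clusters as the whole source are argued against by genes 20 places apart still correlating at 0.0544 (highest shuffle 0.03), and an effect common to the arrays is argued against by 0 of the 7 chromosomes being outside the shuffled range on the depletion array. The bound set beforehand, an upper percentile of shuffled orders, was passed on the depletion array too, by less (0.0218 against 0.0198, with 16 of 1000 shuffles as high). Unlike on the transfection array, the correlation there did not reach farther. It was 0.0185 for genes 5 places apart (upper percentile 0.0191) and -0.0002 for genes 20 places apart (485 of 1000 shuffles as high). A hypothesis is that the transfected and control MSTO-211H cells differed in chromosome copy number, for which the neighbour correlation of 0.0761 met that bound; whether such a difference came from selecting transfected cells is not shown by these data.

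Interferon-stimulated genes were higher on both arrays, although CD26 was lowered on one and raised on the other. A signal-dependent bias stays open: families of tissue-restricted genes, whose probes should be dim in these cells, had medians of -0.01 and 0.03, below the list by at least 0.34 (bootstrap interval 0.09 to 0.61), but the bound set beforehand was missed on the transfection array (margin -0.0162). The tails of these families lean the same way as the list, with 13 of 155 genes at least 2-fold higher and 1 lower on that array (8.39% higher, against 4.09% of all genes) and 10 and 3 of 176 on the depletion array. Genes with a value on the transfection array alone had a median of 0.53, and those with a value on the depletion array alone had 0.07. A gene-specific effect of the dyes, which had the same orientation on both arrays, and a response of the cells to the introduced nucleic acid both stay open, because either may give the observed correlation of 0.38 across 29 members. An effect of the CD26 level on these genes is untested.

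YAP and TEAD targets were higher after CD26 depletion, with CCN2, F3, GADD45A and NT5E past 2-fold. A gene-specific dye effect of the same size on both arrays would give no difference between them, and the difference had a median of 0.65 (0.28 to 1.40) over 15 genes. The list was taken up because it stood apart on the depletion array alone, so this difference partly follows from that choice. It therefore does not decide against a dye effect. For a signal-dependent bias, the list's lower bound lay 0.0415 above the upper bound of the tissue-restricted families on the depletion array. This was past the bound set before that comparison was run. The list was already known to stand apart on this same array, so passing the bound partly follows from that choice. It therefore does not decide against such a bias. Of the 176 genes of these families, 10 were at least 2-fold higher there and 3 lower. The families stand for dim probes only, and without intensities the signal of the list's members is unknown. Families of abundant genes (proteasome, CCT chaperonin and HNRNP genes) had a median of -0.15 on that array (-0.235 to -0.060). A signal-dependent bias therefore stays open, at low signal and at other levels. Different growth states of the depleted and control cultures could not be excluded. As deposited, mitotic genes (-0.19) and replication genes (0.15) lay on opposite sides of 0, so they neither shifted together nor both stayed near 0. Centred on ribosomal protein genes both lay above 0 (0.16 and 0.50), but that centring raised every gene by 0.35, so nothing is drawn from it. An effect of CD26 depletion itself is untested without a replicate or a second depleting sequence.

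Abundant families other than ribosomal proteins (proteasome, CCT chaperonin and HNRNP genes) had medians of -0.15 (-0.235 to -0.060) after depletion and -0.03 (-0.137 to 0.056) after transfection. The interval after depletion lay below 0 and overlapped that of oxidative phosphorylation genes (-0.253 to -0.074). The low values of that list can therefore not be told from a shift of abundant genes in general. Ribosomal protein genes lay lower still on that array (-0.574 to -0.244). Probes without a gene symbol gave 234 values at least 2-fold higher and 129 at least 2-fold lower after depletion, and 326 and 107 after transfection.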
